A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

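The series holds 6 libraries of poly(A) RNA in 3 groups of 2: wild type, rtt109 deletion and hst3 hst4 deletion. Per the labels' protocols, cells grew exponentially in rich medium, RNA was extracted and treated with DNase, mixed with total RNA of Schizosaccharomyces pombe, and made into libraries with a stranded mRNA kit. Groups and replicate numbers were taken from the titles. The strains differ beyond the named deletions, per the labels: wild type and the hst3 hst4 strain carry a tagged subunit of RNA polymerase II and a restored ADE2, which the rtt109 strain lacks, the rtt109 strain alone is labelled with RAD5, and the hst3 hst4 strain is labelled as mating type alpha.

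The deposited table gives coverage, a signal per strand in bins of 50 bases on 16 chromosomes, which the authors scaled to the spike-in, per the file headers. A second set of columns holds the same coverage normalized by the authors to 1, per the file headers, with each strand at a mean of about 1. A further deposited column holds a replication timing score from an earlier publication, per the file headers, whose unit is not stated. Base calling software named in the submitters' processing notes was CASAVA 1.7.0; the aligner and the build of the budding yeast genome are not given in the sources used here. Of 240976 bins, 11670 (4.84%) hold a letter in place of a value, which the file does not define, and were not used (among bins of retrotransposons, 498 of 4134 had values); genes at the mating-type loci were not analysed here.

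Gene positions were those of the table's own features, per bin, and are on the table's build. Names came from the RefSeq table of assembly R64, none of whose coordinates were used: 5871 of 6525 ORFs matched a protein-coding gene, 80 had no usable bin and 5791 had a value. Of the 5211 genes tested, 104 had an ORF in the table under 80% of the RefSeq length, and 21 rested on a single bin. The design planned before the data were examined assumed RefSeq ORFs; the table's features were used in their place because positions on chromosome 11 differ between the builds. ORFs of the Watson strand had 98.0% of their coverage in 1 strand column and those of the Crick strand 98.4% in the other, which set the sense strand.

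A gene's value was its mean sense coverage over bins inside the ORF, without its first and last bin and without bins of introns or shared with another ORF on that strand. The test ran on log2 of the value plus 0.0587, the percentile 5 of values above 0, so fold changes of low genes are understated. The 10% of genes with the lowest mean, 580 genes, were left out. All 6 libraries entered one limma fit, with an empirical Bayes spread, 3 residual degrees of freedom and 37.7 prior degrees of freedom, and an adjusted p under 0.05 (Benjamini-Hochberg) per comparison. limma 3.58.1 ran in R 4.3.3, and tables were read with Python 3.11.15. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation; 33 lists were fixed before the data were examined and 31 had 3 or more tested genes. No list was called in any comparison with the estimated correlation. That setting also refers the camera statistic to the 3 residual degrees of freedom, so the lost calls cannot be laid to correlation among genes alone. For the a-specific genes in the rtt109 deletion the estimated correlation, 0.00299, was below the preset. Their camera adjusted p still went from 0.0473 to 0.560. Antisense values were means on the opposite strand over at least 4 bins with no ORF there.

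Genes were named by a rule fixed before the data were examined. Genes of the genotypes came first. Next came the 8 largest rises and the 8 largest falls past the threshold whose mutant libraries both lay on one side of both control libraries. Then, of each list called or with 3 or more members past the threshold, up to 4 of the largest changes past it were taken, or the 2 smallest p where none passed. An item that this rule gave is not reported here. SSB2, STE3, MF(ALPHA)1 and the genes of the closing section outside this rule were chosen after their values were seen.

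Low coverage values were multiples of a step, taken as the commonest value above 0, which was 0.00397 and 0.00543 in wild type, 0.00771 and 0.00658 in the rtt109 deletion, and 0.00644 and 0.0124 in the hst3 hst4 deletion. A larger step means fewer reads behind the same value; reads span bins, so the numbers of reads are unknown. Replicates correlated at a Pearson r of 0.964, 0.973 and 0.951 across genes, and no gene had the same value above 0 in both libraries of a group. Replicate 1 of the hst3 hst4 deletion correlated best with replicate 1 of the rtt109 deletion (0.961).

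The fit was tested on simulated data over 5211 genes with 200 changed genes. Changes of 1, 2 and 3 on the log2 scale were recovered in 6.75%, 68.3% and 90.0% for the rtt109 deletion against wild type, and in 5.25%, 71.3% and 90.0% for the hst3 hst4 deletion against wild type. About 3.03% and 3.19% of calls were false. Each simulated gene's spread was its own estimate from these libraries, on 3 residual degrees of freedom. Spreads thus differed more between simulated genes than the 37.7 prior degrees of freedom of the fit imply. The rates of recovery and of false calls therefore need not hold for the calls in the data. For the rtt109 deletion against wild type, camera recovered 5 of 5 shifted lists and called 1 of 145 others. The simulated genes varied independently and their lists were random. In the data the estimated correlation was 0.344 for general stress genes and 0.654 for rRNA processing genes. This rate of false lists therefore does not cover lists of correlated genes. A change of 1 on the log2 scale was mostly not recovered in the simulation, and the smallest absolute log2 fold change called in the data was 1.22.

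Alternatives were other scales, pseudocounts, filters and summaries of bins, a trend in the spread, the 4 libraries of a comparison alone, a replicate block, and each library left out in turn. Added after seeing the data were the authors' second scale, removal of a trend with ORF length, and subtraction of antisense coverage in proportion to sense coverage.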

Results

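Poly(A) RNA was measured in exponentially growing budding yeast by strand-specific sequencing, with RNA of fission yeast mixed in as a spike-in. There were 3 groups of 2 libraries each: wild type, a deletion of RTT109, and a double deletion of HST3 and HST4. Rtt109 is the acetyltransferase of lysine 56 of histone H3, and Hst3 and Hst4 are the sirtuins that remove this mark, so the groups lack the mark or retain too much of it. The values were spike-in scaled coverage in bins of 50 bases, summing to 678558 and 784679 in the wild-type libraries, 474278 and 611350 in the rtt109 deletion, and 763469 and 654763 in the hst3 hst4 deletion. After the filter on low values, 5211 genes were tested. Nothing in the labels says whether replicates came from separate cultures. The limma p-values thus measure at most the spread between these libraries, pooled in part across genes. Camera p-values at the preset correlation set the genes of a list against other genes. They rest on the spread among genes, and small ones are no measure of agreement between libraries or cultures.

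The deleted genes were examined first in every library. RTT109 (YLL002W, chromosome 12, 146301 to 147650) had a mean coverage of 0.763 and 0.830 in the wild-type libraries and 0.996 and 0.856 in the hst3 hst4 deletion. In the rtt109 deletion it had 0.00123 and 0.00342. HST3 (YOR025W, chromosome 15, 378251 to 379650) had 1.34 ± 0.0287 (SD, n = 2) in wild type, 0.963 ± 0.347 (SD, n = 2) in the rtt109 deletion and 0.0116 ± 0.00222 (SD, n = 2) in the hst3 hst4 deletion. HST4 (YDR191W, chromosome 4, 842351 to 843500) had 0.571 ± 0.143 (SD, n = 2) in wild type, and 0.0617 and 0.00648 in the hst3 hst4 libraries. BAR1, the protease that degrades alpha factor, is labelled as deleted in each strain and was listed at 0 in all 6 libraries. The hst3 hst4 strain is labelled as mating type alpha, yet the a-specific receptor gene STE2 had 23.0 ± 0.531 (SD, n = 2) there against 22.9 ± 10.4 (SD, n = 2) in wild type. The alpha-specific genes STE3 and MF(ALPHA)1 had 0.0197 ± 0.00168 and 0.336 ± 0.0127 in that strain, against 0.00963 ± 0.00941 and 0.0323 ± 0.00735 in wild type (SD, n = 2 each). The a-specific transcripts of this group thus go against its mating-type label, while the low MF(ALPHA)1 values lay above wild type. STE3 rests on 4 bins, with 0.0209 and 0.0186 in the hst3 hst4 libraries and 0.00298 and 0.0163 in wild type. These values lie near the steps of the hst3 hst4 libraries, 0.00644 and 0.0124, and are too low to read as a difference.

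The first comparison asked which transcripts differ without Rtt109. The largest rise was in HSP12 (YFL014W, chromosome 6, 107251 to 107650), a membrane-protecting stress protein, which went from 2.07 ± 2.14 to 68.8 ± 20.7 (SD, n = 2 each), a log2 fold change of 5.49 ± 0.49 (SE). The cell wall gene PIR3 (YKL163W, chromosome 11, 144451 to 145450) went from 0.228 ± 0.043 to 9.21 ± 1.90 (SD, n = 2 each), a log2 fold change of 5.01. GRE1 rose by 4.54, the small heat shock protein gene HSP26 by 3.78, PHM8 by 3.74, DDR2 by 3.69, MOH1 by 3.65 and the pyridoxine gene SNO1 by 3.54 on the log2 scale. Among genes that fell, HO, the mating-type switching endonuclease (YDL227C, chromosome 4, 46301 to 48100), went from 3.48 ± 1.91 to 0.364 ± 0.0145 (SD, n = 2 each), a log2 fold change of -2.95. The other large falls were in SPS4 (-2.08), the ribosome biogenesis gene TSR2 (-2.05), RPS9A (from 29.1 ± 13.8 to 7.11 ± 2.82, SD, n = 2 each), the histone H2A gene HTA1 (-1.92), the nicotinamide riboside transporter NRT1 (-1.91), the nicotinic acid transporter TNA1 (-1.89) and ALT2 (-1.87). By limma with Benjamini-Hochberg adjustment, adjusted p ran from 4.73e-13 for PIR3 to 0.00476 for ALT2. RPS9A has a near-identical copy, RPS9B, so its value is uncertain, as are those of the paired histone and ribosomal protein genes below.

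Of 24 general stress genes, 11 rose, 0 fell and 13 did not pass, and 18 rose when adjusted over the list alone. Their median log2 fold change was 1.15 against -0.37 over all genes, and the glycogen phosphorylase gene GPH1 (2.45) and SPI1 (2.14) were among them. The camera test gave an adjusted p of 3.46e-31 with its preset correlation, and adjusted p = 0.342 with an estimated correlation. Of 8 core histone genes, 3 fell, namely HTA1, HTB1 (-1.57) and HTB2 (-1.41), and 5 did not pass; 7 fell when adjusted over the list alone. Histone genes stood below other genes (camera adjusted p = 0.000104; adjusted p = 0.588 with an estimated correlation). Ribosomal protein genes had a median of -0.80, with 2 of 136 falling, RPS9A and RPL7A (-1.41), and 134 not passing; 1 fell when adjusted over the list alone. Their adjusted p was 5.03e-12, and adjusted p = 0.665 with an estimated correlation. The 73 rRNA processing genes had a median of -0.79 with none past the threshold over all genes or over the list alone (adjusted p = 3.00e-07, and adjusted p = 0.683 with an estimated correlation), UTP8 at -1.15 and RRP9 at -1.11 among them.

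Some lists of metabolism stood above other genes without RTT109, among them adenine, amino acid and sulfur genes. Of 14 adenine and one-carbon genes, ADE17 (1.62) and ADE12 (1.41) rose and 12 did not pass, with 2 rising when adjusted over the list alone (adjusted p = 5.69e-05; adjusted p = 0.560 with an estimated correlation). By the labels only the rtt109 strain lacks a restored ADE2. In the hst3 hst4 strain, where it is restored, the same list had a median of 0.29 and did not pass (adjusted p = 0.0545), but did with each library centred (0.0260), without either rtt109 library (0.0240) and without replicate 1 of the hst3 hst4 deletion (0.0196). The 14 genes of the tricarboxylic acid cycle had a median of 0.62 with 0 past the threshold and 3 when adjusted over the list alone (adjusted p = 3.00e-07; adjusted p = 0.560 with an estimated correlation). CIT1, encoding citrate synthase, had a log2 fold change of 1.15 (adjusted p = 0.0784) and SDH2 one of 1.04 (adjusted p = 0.113). The 29 respiratory chain genes had a median of 0.07 with 0 past the threshold either over all genes or when adjusted over the list alone (adjusted p = 0.00222; adjusted p = 0.665 with an estimated correlation), ATP1 at 0.57 and COR1 at 0.55. SER3 (1.31) was the single gene of 40 for amino acid synthesis to rise, and MET28 (1.78) the single one of 18 for sulfur; 1 rose in each when adjusted over the list alone. Their adjusted p values were 2.38e-06 and 5.97e-06, and adjusted p = 0.665 and adjusted p = 0.560 with an estimated correlation. Of 9 phosphate genes, the transporter PHO84 (3.44 ± 0.44, SE) and the phosphatase PHO5 (1.90 ± 0.46, SE) rose, and 2 when adjusted over the list alone, although the median of the list was -0.22 and its mean 0.34 (adjusted p = 0.0450, and adjusted p = 0.683 with an estimated correlation). The rtt109 libraries differed, with 0.364 and 2.01 for PHO84 and 0.359 and 2.42 for PHO5, and without replicate 2 of that group the log2 fold changes were 2.30 (adjusted p = 0.133) and 0.62 (adjusted p = 0.336). They were 4.59 (adjusted p = 0.0164) and 3.19 (adjusted p = 0.0662) without replicate 1 of that group. The call of the list was lost with each library centred (adjusted p = 0.198) and without replicate 2 of the rtt109 deletion (adjusted p = 0.328). Of 15 iron genes, FIT2 rose (1.67) and ATX1 (-1.55), FRE1 (-1.55) and FTR1 (-1.51) fell, and 1 rose and 3 fell when adjusted over the list alone, with an adjusted p of 0.628 for the list.

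Positional and cell-cycle lists were also tested in the rtt109 deletion. Of 92 genes within 20 kb of a chromosome end, 9 rose, 1 fell and 82 did not pass, and 14 rose and 4 fell when adjusted over the list alone. Among them were the hexokinase gene HXK1 (1.78), YPS6 (from 0.119 ± 0.00513 to 0.521 ± 0.103, SD, n = 2 each), SNZ3 (1.56), which has near-identical copies, and MSC1 (1.42). The adjusted p was 1.98e-05, and adjusted p = 0.588 with an estimated correlation. PAU2 (2.07) and PAU23 (1.28), of a near-identical family whose values are uncertain, rose among 4 seripauperin genes, and 2 when adjusted over the list alone (adjusted p = 5.69e-05; adjusted p = 0.342 with an estimated correlation). Of 416 genes within 2 kb of an annotated origin, 17 rose and 10 fell, SIP18 (3.51), DPA10 (3.45), XBP1 (2.64) and HO among them, and 24 rose and 14 fell when adjusted over the list alone; the list did not pass (adjusted p = 0.129). EGT2 (-1.38) was the one of 13 late mitotic genes to fall, against 8 falling and 1 rising when adjusted over the list alone (adjusted p = 0.0149; adjusted p = 0.665 with an estimated correlation). The 13 genes of G1 had a median of -0.82 with 0 past the threshold and 5 falling when adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.709 with an estimated correlation); YOX1 had -1.10 and TOS4 -0.99. Without replicate 1 of wild type the late mitotic list had an adjusted p of 0.195, and without replicate 2 of wild type the G1 list had 0.126.

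Of the remaining lists of the rtt109 deletion, 6 a-specific genes had a median of -0.85, with 0 past the threshold and 3 falling when adjusted over the list alone (adjusted p = 0.0473; adjusted p = 0.560 with an estimated correlation). MFA2 had a log2 fold change of -1.20 and STE2 one of -1.13. This call was lost with the length trend removed (adjusted p = 0.0629), without replicate 1 of wild type (0.121), without replicate 2 of the rtt109 deletion (0.159) and without either hst3 hst4 library (0.0591). The 42 replication genes had a median of -0.49, with 0 past the threshold over all genes or when adjusted over the list alone (adjusted p = 0.0450; adjusted p = 0.827 with an estimated correlation), ORC1 at -0.94 and RFC1 at -0.89. It was lost with the length trend removed (adjusted p = 0.0723), without replicate 2 of wild type (0.321) and without either hst3 hst4 library (0.0591). Among 10 pheromone genes 2 fell, and 6 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0520), but did with each library centred (adjusted p = 0.0453). Among 10 genes of NAD synthesis NRT1 and TNA1 fell, and 2 when adjusted over the list alone (adjusted p = 0.220).

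In all, limma called 179 genes in the rtt109 deletion, 130 higher and 49 lower, and 1043 at an unadjusted p under 0.05. The 49 include the deleted gene RTT109 (-3.81). On a scale with each library centred on its median the split was 153 higher and 11 lower, with quantile normalization 131 and 18, and on the authors' scale with each strand at a mean of 1 it was 245 and 10. The median log2 fold change was -0.37, with the 4 pairs of libraries between -0.63 and -0.07, and an exact permutation test of the library medians gave a two-sided p of 0.333, the smallest that 2 against 2 allows. The count was 4 with no filter and 2 with a pseudocount 10 times larger, 4 and 3 without replicate 1 or 2 of the rtt109 deletion, and 84 without replicate 2 of wild type. The split turned without replicate 1 of wild type, to 120 higher and 131 lower. All 4 and 3 genes called without an rtt109 library were among the 179. The count depends on the estimated prior degrees of freedom of the spread, 37.7. Held at 4.42, the value without an rtt109 library, and with the prior variance unmoved, the same fit called 7. This test was chosen after the counts were seen.

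**Figure D1:**
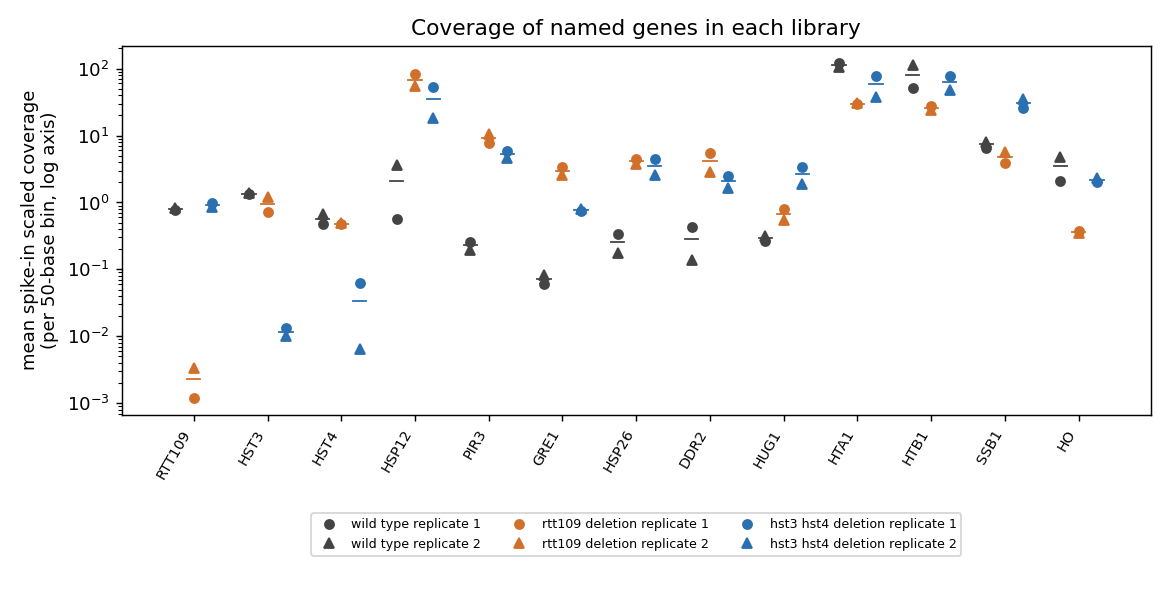
Mean spike-in scaled coverage per 50-base bin, on a log axis, of 13 genes in each of the 6 libraries; circles are replicate 1, triangles are replicate 2 and dashes are group means. HSP12 lies at 68.8 on average in the rtt109 deletion and at 35.4 in the hst3 hst4 deletion, above both wild-type libraries.

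The second comparison asked which transcripts differ without Hst3 and Hst4. The largest rises were in HSP12, which reached 35.4 ± 24.2 (SD, n = 2), a log2 fold change of 4.37 ± 0.49 (SE), in PIR3 (4.20) and in HSP26 (3.51), which also rose in the rtt109 deletion. The zinc transporter gene ZRT1 (YGL255W, chromosome 7, 21001 to 22200) went from 2.64 ± 1.66 to 31.6 ± 28.0 (SD, n = 2 each), a log2 fold change of 3.35. HUG1 (YML058W-A, chromosome 13, 158801 to 159050), a target of the DNA damage checkpoint, went from 0.290 ± 0.0397 to 2.63 ± 1.02 (SD, n = 2 each), a log2 fold change of 2.90. The sulfiredoxin gene SRX1 rose by 2.78, DDR2 by 2.75 and GPH1 by 2.70. Outside the deleted genes 5 genes fell: YOL014W (-1.88), TSR2 (-1.69), PHM6 (-1.51), the ammonium permease gene MEP2 (-1.45) and the iron oxidase gene FET3 (-1.37). By limma, adjusted p ran from 7.00e-11 for PIR3 to 0.0364 for FET3.

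Of 24 general stress genes, 12 rose and 12 did not pass, and 18 rose when adjusted over the list alone, with HXK1 (2.05) among them (camera adjusted p = 5.35e-28; adjusted p = 0.323 with an estimated correlation). Of 14 genes induced by DNA damage, 2 rose, HUG1 among them, and 12 did not pass, and 5 rose when adjusted over the list alone. Their median log2 fold change was 0.72, and the adjusted p was 2.52e-07, with adjusted p = 0.323 with an estimated correlation. In the rtt109 deletion the same list had a median of 0.19 with 0 of 14 past the threshold, also over the list alone (adjusted p = 0.00556; adjusted p = 0.588 with an estimated correlation). There HUG1 had a log2 fold change of 1.05 and RNR1 one of -0.85. Relative to the median over all genes, the list lay 0.68 higher in the hst3 hst4 deletion and 0.56 higher in the rtt109 deletion. Between the mutants it did not pass (camera adjusted p = 0.0721), so its rise is not particular to the hst3 hst4 deletion. Histone genes had a median of -0.57 with 0 of 8 past the threshold, also over the list alone (adjusted p = 0.000292; adjusted p = 0.849 with an estimated correlation); HTA1 had -1.05 and HTA2 -0.89. FET3 fell among 15 iron genes, and 3 when adjusted over the list alone (adjusted p = 0.000161; adjusted p = 0.323 with an estimated correlation).

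Further lists stood apart from other genes in the hst3 hst4 deletion. The tricarboxylic acid cycle genes had a median of 0.75 (adjusted p = 3.82e-06; adjusted p = 0.561 with an estimated correlation), with SDH2 at 1.09 and SDH4 at 0.92. Respiratory chain genes had a median of 0.39 (adjusted p = 0.0184; adjusted p = 0.849 with an estimated correlation), with ATP7 at 0.73 and ATP5 at 0.69. The rRNA processing genes had a median of -0.27 (adjusted p = 1.74e-06) and ribosomal protein genes one of -0.10 (adjusted p = 0.000161), both with adjusted p = 0.849 with an estimated correlation. NOP15 had a log2 fold change of -0.79, NOP53 -0.80, RPS21A -0.85 and RPS17B -0.83. Late mitotic genes had a median of -0.36 (adjusted p = 0.0136; adjusted p = 0.849 with an estimated correlation), with EGT2 at -0.72 and SCW11 at -0.57. None of these 5 lists had a member past the threshold, over all genes or over the list alone. Single libraries carried several of these calls. Without replicate 2 of wild type the adjusted p was 0.199 for the respiratory chain, 0.277 for rRNA processing and 0.0816 for ribosomal proteins. Without replicate 1 of wild type it was 0.248 for late mitotic genes. Without replicate 1 of the hst3 hst4 deletion it was 0.964 for the respiratory chain, 0.171 for late mitotic genes and 0.0569 for iron genes. Without replicate 2 of the hst3 hst4 deletion it was 0.0877 for ribosomal proteins and 0.0764 for histones. Removal of the length trend gave 0.0616 for the respiratory chain.

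PAU2 (1.93) and PAU17 (1.30) rose among 4 seripauperin genes, and 4 when adjusted over the list alone (adjusted p = 1.74e-06; adjusted p = 0.323 with an estimated correlation). Of the genes near chromosome ends 6 rose and 0 fell, HXK1, YPS6 (1.86), YOL160W (1.82) and YOL163W (1.82) among them, and 11 rose when adjusted over the list alone (adjusted p = 0.00642; adjusted p = 0.849 with an estimated correlation). Of the 416 genes near origins 24 rose and 1 fell, and 29 and 1 when adjusted over the list alone (adjusted p = 0.0148; adjusted p = 0.925 with an estimated correlation). ZPS1 (3.21), DPA10 (2.70), CDA1 (2.30) and SIP18 (2.08) were the largest of these, and ZPS1 had 36.5 and 0.952 in the hst3 hst4 libraries against 0.302 and 1.14 in wild type. Without replicate 1 of the hst3 hst4 deletion the adjusted p was 0.171 for genes near origins and 0.0533 for those near chromosome ends, and without replicate 2 of wild type it was 0.0816 for genes near origins.

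limma called 129 genes in the hst3 hst4 deletion, 122 higher and 7 lower, and 416 at an unadjusted p under 0.05. The median log2 fold change was 0.03, with the 4 pairs between -0.13 and 0.26, and the exact permutation test of the library medians gave a two-sided p of 1. The count was 54 with each library centred on its median, 2 with no filter, 1 with a pseudocount 10 times larger and 80 without replicate 1 of wild type, of which 73 were among the 129. It was 2 without either library of the rtt109 deletion, which enters this comparison only through the spread, and 2 in the fit of all 6 libraries with the prior degrees of freedom held at 4.42. The median log2 ratio of coverage at the 5′ to the 3′ end of ORFs of 2000 bases or more was -2.03 and -1.74 in this group, -1.73 and -1.19 in the rtt109 deletion and -1.16 and -1.53 in wild type.

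**Figure D2:**
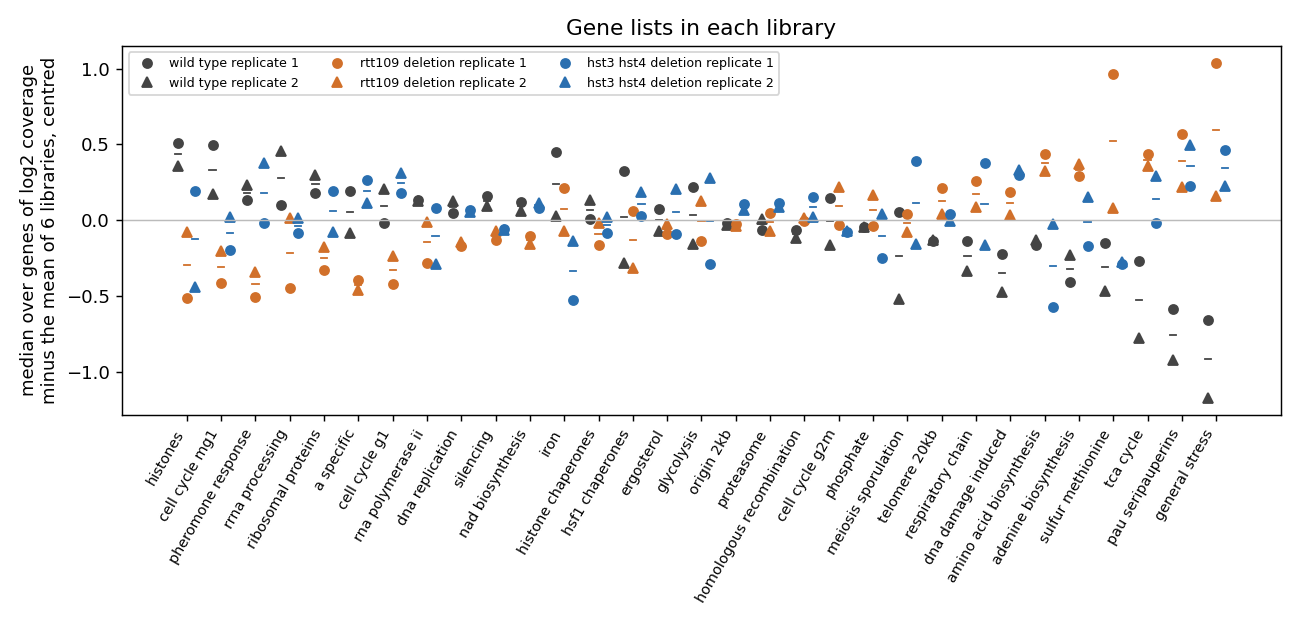
Each point is the median over a list's genes of log2 coverage minus the mean of the 6 libraries, after centring each library on its median; lists are ordered by the difference of the rtt109 deletion from wild type and dashes are group means. The general stress list is at -0.66 and -1.17 in wild type and above 0 in the 4 mutant libraries.

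The mutants were compared with each other to ask where the strains without the acetyltransferase and without the deacetylases differ. Per the labels these strains also differ in the tagged RNA polymerase II subunit, the restored ADE2, RAD5 and the labelled mating type. Differences between them, those of adenine genes included, thus cannot be laid to the named deletions alone. The ribosome-associated chaperone gene SSB1 (YDL229W, chromosome 4, 44101 to 46000) had 30.2 ± 6.46 in the hst3 hst4 deletion, 4.81 ± 1.35 in the rtt109 deletion and 7.36 ± 1.05 in wild type (SD, n = 2 each). It was higher in the hst3 hst4 deletion than in the rtt109 deletion by a log2 fold change of 2.65 ± 0.37 (SE), and its near-identical copy SSB2 makes the value uncertain. Also higher were HO (2.39), YHR140W (1.98), ZRT1 (1.95), the copper transporter CTR1 (1.95), AMF1 (1.91), the inositol synthesis gene INO1 (1.88) and HUG1 (1.85). Lower were HSP30 (-3.09), TDA6 (-2.61), PHO84 (-2.57), QDR2 (-2.41), BAG7 (-2.40), MNC1 (-2.36), the polyamine transporter TPO2 (-2.24) and RTC2 (-2.23). By limma, adjusted p ran from 1.85e-05 for SSB1 to 0.0240 for ZRT1.

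Genes of amino acid synthesis stood lower in the hst3 hst4 deletion than in the rtt109 deletion, with a median of -0.29 against 0.41 over all genes on the tested scale (camera adjusted p = 1.58e-17; adjusted p = 0.680 with an estimated correlation). None of the 40 passed over all genes and 5 fell when adjusted over the list alone; HIS4 had -1.23 and BAT1 -1.24. Sulfur genes had a median of -0.35 with 0 passing over all genes or when adjusted over the list alone (adjusted p = 1.07e-08; adjusted p = 0.597 with an estimated correlation), MET14 at -1.12 and STR3 at -0.98; without replicate 1 of the rtt109 deletion this list had an adjusted p of 0.0564. The 14 adenine genes had a median of 0.01 and a mean of -0.04, with 0 past the threshold and 1 falling when adjusted over the list alone (adjusted p = 0.00363; adjusted p = 0.757 with an estimated correlation), ADE12 at -1.18 among them, and an adjusted p of 0.307 without replicate 1 of the hst3 hst4 deletion. Iron genes had a median of -0.22 and a mean of -0.02 with 0 past the threshold or when adjusted over the list alone (adjusted p = 0.00282; adjusted p = 0.597 with an estimated correlation), ATX1 at 1.11 and SIT1 at -0.97 among them, and 0.217 without that library. PHO84 was the single phosphate gene to fall, and 1 fell when adjusted over the list alone; the median of that list was 0.33 and its mean -0.17 (adjusted p = 0.0103; adjusted p = 0.807 with an estimated correlation), and its call was lost with each library centred (0.0848) and without replicate 2 of the rtt109 deletion (0.379). Ribosomal protein genes stood higher, with a median of 0.68 and 0 past the threshold or when adjusted over the list alone (adjusted p = 2.19e-06; adjusted p = 0.896 with an estimated correlation), RPL18B at 1.15 among them.

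Genes of the cell cycle and of mating were compared in the same way. Of 13 genes of G1, YOX1 (1.74) rose, and 9 when adjusted over the list alone (adjusted p = 9.93e-05; adjusted p = 0.807 with an estimated correlation). Of 6 a-specific genes, ASG7 (1.49) and the a-factor gene MFA2 (1.47) rose, and 4 when adjusted over the list alone (adjusted p = 0.00139; adjusted p = 0.597 with an estimated correlation). FAR1 (1.44) rose among 10 pheromone genes, and 5 when adjusted over the list alone (adjusted p = 0.00669; adjusted p = 0.757 with an estimated correlation), with an adjusted p of 0.178 without replicate 2 of the hst3 hst4 deletion. NRT1 (1.74) and BNA2 (1.55) rose among 10 genes of NAD synthesis, and 4 when adjusted over the list alone (adjusted p = 0.0198; adjusted p = 0.680 with an estimated correlation); the list had 0.102 without replicate 2 of the rtt109 deletion and 0.133 without replicate 2 of the hst3 hst4 deletion. CDC6 (1.49) rose among 42 replication genes, and 1 when adjusted over the list alone (adjusted p = 0.0306; adjusted p = 0.911 with an estimated correlation); the list had 0.143 without replicate 1 of the rtt109 deletion and 0.0891 and 0.0880 without replicate 1 or 2 of the hst3 hst4 deletion. SPI1 fell (-2.04) as the single general stress gene, and 1 fell when adjusted over the list alone; that list's median was 0.18 and its mean -0.05, against the 0.41 over all genes (adjusted p = 0.000558; adjusted p = 0.807 with an estimated correlation). Without replicate 1 of the rtt109 deletion the general stress list turned upward (adjusted p = 0.509). Of the genes near chromosome ends, YOL160W (1.66), PAD1 (1.57) and YEL073C (1.47) rose and SRY1 (-1.63) fell, and 6 rose and 4 fell when adjusted over the list alone. Their median was 0.25, and they stood below other genes (adjusted p = 0.0204; adjusted p = 0.896 with an estimated correlation); the list had 0.222 without replicate 1 of the rtt109 deletion and 0.0975 and 0.0677 without replicate 1 or 2 of the hst3 hst4 deletion.

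limma called 72 genes between the mutants, 41 higher and 31 lower in the hst3 hst4 deletion, and 812 at an unadjusted p under 0.05. The calls include the deleted genes RTT109 (4.01), HST3 (-3.82) and HST4 (-2.60), and the genotype gene LEU2 (-1.63). With each library centred on its median the counts were 2 higher and 12 lower, with quantile normalization 5 and 20, and with each strand at a mean of 1 they were 4 and 22. On the spike-in scale without replicate 1 of the hst3 hst4 deletion they were 27 and 43, so the direction of the majority rests on the scale and on that library. The median log2 fold change was 0.42, with the 4 pairs between 0.19 and 0.66, and the exact permutation p was 0.333 (two-sided). The count was 1 with no filter, 0 with a pseudocount 10 times larger, 7 over the last 500 bases of each ORF, 2 and 0 without replicate 1 or 2 of the rtt109 deletion, and 2 with the prior degrees of freedom held at 4.42.

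Fold changes of the mutants against wild type were related across genes, with a Pearson r of 0.667 over 5211 genes, which are not independent replicates. Simulated groups with no change, both compared with the same simulated wild-type libraries, gave 0.501 ± 0.0107 (SD over 100 simulations). The covariance was 0.190 against a simulated 0.0708. Both comparisons called 64 genes higher and 1 gene lower, TSR2. Independent lists of these sizes would share 3.04 and 0.0658, a figure that leaves out the shared wild-type libraries. The simulated groups shared 0 calls in 20 simulations, but hold no effects to call, so neither figure measures a shared effect. No gene was called in opposite directions. With 2 wild-type libraries the controls were not split, as each part would hold a single library, so part of the excess in shared calls may come from sharing them. The covariance lay 0.119 above the simulated one, which holds the sharing of independent noise in the wild-type libraries. A departure common to both wild-type libraries would also enter both comparisons. The simulation does not hold it, so the excess cannot be laid to an effect shared by the mutants.

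Antisense coverage of ORFs was tested in 4895 ORFs. limma called 0 in each of the 3 comparisons, with 154, 160 and 300 at an unadjusted p under 0.05. The libraries differed in antisense background: over 534 genes with the highest sense coverage, antisense was 1.52% and 0.0727% of sense in the wild-type libraries, 0.582% and 0.129% in the rtt109 deletion, and 0.177% and 0.982% in the hst3 hst4 deletion.

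**Figure D3:**
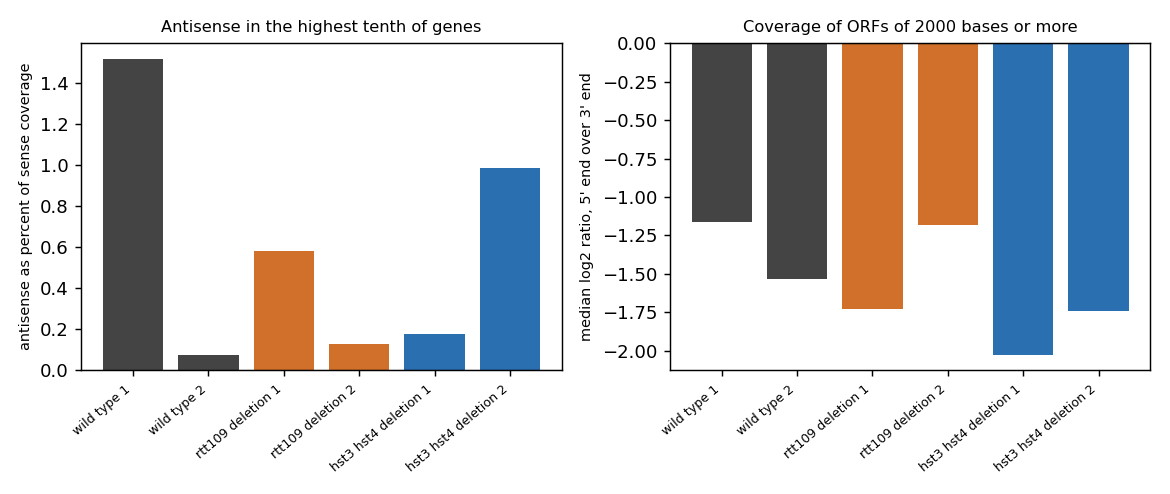
Bars give, for each library, antisense coverage as a percent of sense coverage in the 534 genes with the highest sense coverage (left) and the median log2 ratio of 5′ to 3′ coverage in ORFs of 2000 bases or more (right). Antisense runs from 0.0727% to 1.52% within wild type, and the 5′ to 3′ ratio from -2.03 to -1.16 over the 6 libraries.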

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

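The tests of explanation in this part were chosen after the values were seen. Of 76 genes that the naming rule gave in the comparisons with wild type, 14 differed between the mutants by limma (adjusted p under 0.05), 8 higher and 6 lower in the hst3 hst4 deletion. On the log2 scale the differences were -1.87 for GRE1, -1.62 for PHM8, -1.51 for SNO1, 2.39 for HO, 1.74 for NRT1, 1.95 for ZRT1, 1.85 for HUG1 and -1.46 for MEP2. They were 1.47 for MFA2, -2.04 for SPI1, -2.57 for PHO84, 1.74 for YOX1, 1.66 for YOL160W and 2.80 for ZPS1. Over all tested genes, 72 of 5211 were called between the mutants. The 76 were mostly named for large changes against wild type in these same mutant libraries. A difference between the mutants is thus more likely among them, and the 14 are no independent result. Leaving out either library of the rtt109 deletion leaves 2 or 0 of the 72 calls between the mutants, and the fit of all 6 libraries with its prior degrees of freedom held at 4.42 called 2.

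Coverage in bins annotated as rRNA, which no comparison used, was above both wild-type libraries (0.515 and 0.161 in sum over 31 bins) in all 4 mutant libraries, of which the lowest had 1.31. These sums are at most 0.000401% of a library's coverage, and the differences were not tested.

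As a list, general stress genes stood above other genes in both mutants, with 11 and 12 of 24 past the threshold. The list was not called with an estimated correlation (camera adjusted p = 0.342 in the rtt109 deletion and 0.323 in the hst3 hst4 deletion). UGP1 had a log2 fold change of -0.38 in the rtt109 deletion and SPI1 one of 0.11 in the hst3 hst4 deletion. The spike-in scale does not account for the higher list. After centring each library, the list lay 1.26 above wild type in the hst3 hst4 deletion and 1.51 in the rtt109 deletion, with a spread of 0.428 (SD) within groups. Loss of 5′ coverage or gene length does not either, since the smallest difference with the length trend removed or over the last 500 bases was 1.20, with a spread of 0.427 (SD). A difference in growth state between cultures may be the source, with ribosomal protein genes at -0.49 and -0.18 from wild type in the rtt109 and hst3 hst4 deletions after centring (spread 0.137, SD) and rRNA processing genes at -0.49 and -0.31 (0.240), so the values in the hst3 hst4 deletion lie near the spread; each genotype had its own cultures, so growth state and genotype cannot be told apart. The genotype itself stays open and untested.

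The libraries labelled hst3 hst4 and mating type alpha held a-specific transcripts at a median of 127.7% of wild type over 6 genes, where alpha cells would have nearly none. An exchange with another group is argued against by HST3, at 0.862% of wild type, and by RTT109 at the wild-type level. The alpha-factor gene MF(ALPHA)1 was at 1039% of wild type, though at a low level (0.327 and 0.345). Other alpha-specific genes lay above wild type by less, with SAG1 at 0.535 against 0.400 and AFB1 at 1.09 against 0.585. In the rtt109 deletion MF(ALPHA)1 also lay above wild type (0.0582 and 0.0929 against 0.0375 and 0.0271), as did SAG1 at 0.516 and AFB1 at 0.782. SAG1 thus hardly differed between the mutants, with 0.516 ± 0.133 in the rtt109 deletion and 0.535 ± 0.104 in the hst3 hst4 deletion (SD, n = 2 each). A small share of alpha cells or partial loss of silencing could give the MF(ALPHA)1 values in the hst3 hst4 deletion. With no alpha culture these 2 explanations cannot be told apart. A wrong entry of the mating type in the strain label is a candidate explanation that the 127.7% leaves open.

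Antisense coverage differed between libraries of a group, from 1.52% to 0.0727% of sense in wild type. The excess of one library over its partner was 24.9 times as large in genes of the highest sense coverage as in those below the median in wild type, 53.3 times in the rtt109 deletion and 33.4 times in the hst3 hst4 deletion. This is consistent with incomplete strand marking of sense RNA, and argues against genomic DNA, which would add the same amount to genes of high and low sense coverage. If so, the 0 antisense calls were made on values that partly hold sense signal; antisense RNA proper to genes of high sense coverage was not tested against this.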

How the results depend on the processing

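The scale with each strand at a mean of 1, the removal of a length trend and the subtraction of strand leakage were chosen after seeing the data. Of 211 values of counts, medians and lists under an alternative, 132 stayed within 1.5 times or within the spread. The 211 include counts of antisense calls, which stayed at 0, and median shifts. The total thus does not show that counts of genes called were stable. Most counts of genes per direction moved by more than 1.5 times. Of 2574 values for 130 named results, 1845 kept their status, 687 lost a call, 42 gained one and 0 reversed. A kept status includes results called in neither fit. With a pseudocount 10 times larger, 39 of the 130 kept their status and 91 lost their call.

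Counts are given as higher and lower. For the rtt109 deletion (130 and 49) they were 2 and 0 with a pseudocount 10 times larger, 3 and 1 with no filter, and 76 and 19 over the last 500 bases. The lower count was 11 when centred, 18 with quantile normalization, 102 with a trend in the spread, 80 with the 4 libraries alone and 92 with the length trend removed. Each strand at a mean of 1 gave 245 and 10. Without single libraries the counts ran from 2 to 157 and from 1 to 131.

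For the hst3 hst4 deletion (122 and 7) they were 51 and 3 when centred, 28 and 3 with quantile normalization, 1 and 0 with the larger pseudocount, 1 and 1 with no filter or with the 4 libraries alone, and 77 and 2 over the last 500 bases. The higher count was 64 without the lowest 25% of genes; the lower count was 12 with a pseudocount 10 times smaller, 14 with a trend and 3 with each strand at a mean of 1. Without single libraries they ran from 1 to 118 and from 1 to 25.

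Between the mutants (41 and 31) they were 2 and 12 when centred, 5 and 20 with quantile normalization, 0 and 0 with the larger pseudocount, 1 and 0 with no filter, 4 and 3 over the last 500 bases, and 121 and 50 with a trend. The higher count was 65 with the smaller pseudocount, 4 with each strand at a mean of 1 and 62 with the length trend removed. Without single libraries they ran from 0 to 53 and from 0 to 43; where a group kept 1 library, it was assumed to vary like the others.

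The prior degrees of freedom were 37.7 in the planned fit, 2.40 with no filter, 3.72 with the larger pseudocount, 4.42 without an rtt109 library, 6.63 when centred and 8.23 with each strand at a mean of 1. In a test chosen after the counts were seen, the planned fit called 7, 2 and 2 genes with the value held at 4.42, and 3, 0 and 0 at 2.40. Held at 37.7, the count was 1040, 406 and 700 with no filter, 582, 116 and 297 with the larger pseudocount, and 133, 180 and 77, and 353, 180 and 57, without replicate 1 or 2 of the rtt109 deletion. These refits moved the prior degrees of freedom alone and kept each fit's prior variance, which limma estimates together with them. With no filter the 1040 calls exceeded the 980 genes at an unadjusted limma p under 0.05 in that setting's own fit. The refits thus show how strongly the counts depend on the prior degrees of freedom, not why they are low in these settings. For the other settings the cause was not tested. Differences between replicates correlated at -0.227 between wild type and the rtt109 deletion, 0.0639 between wild type and the hst3 hst4 deletion, and 0.222 between the mutants. Replicate numbers thus showed no pairing common to the 3 groups, but a batch shared by the mutants is not excluded. With the replicate number as a block the counts were 81 and 20, 91 and 3, and 5 and 7, and with block and centring 263 and 26, 117 and 9, and 15 and 79. Lists called by camera, 17, 12 and 13, ran from 15 to 17, 8 to 14 and 10 to 13 without single libraries and were 0, 0 and 0 with an estimated correlation. Median shifts ran from -0.53 to -0.21, -0.06 to 0.21 and 0.29 to 0.59. limma called 0 antisense ORFs under each alternative run, against 154, 160 and 300 at an unadjusted p under 0.05. Centring cannot move the correlation of the mutants, 0.667. With 2 libraries a group, a change of 1 on the log2 scale was recovered in 6.75% of simulated genes for the rtt109 deletion.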

Other observations

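LEU1 and OAC1, outside the fixed lists, were chosen after their values were seen, and no list of such genes was tested. LEU2, also outside those lists, was among the genes of the genotypes fixed before the data were examined. LEU1 had 61.8 and 63.1 in the rtt109 libraries, 20.3 and 15.0 in the hst3 hst4 libraries, and 17.8 and 37.3 in wild type, a log2 fold change of -1.84 between the mutants (limma adjusted p = 0.00577). LEU2 (-1.63, adjusted p = 0.0105) and the mitochondrial carrier gene OAC1 (-1.50, adjusted p = 0.0411) fell with it. Against wild type none of the 3 passed in the rtt109 deletion, where LEU1 had 1.28 (adjusted p = 0.0515). LEU9, of the fixed list of amino acid synthesis, had 0.19 between the mutants.

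SSB1 and HO lie close together on chromosome 4, and both were higher in the hst3 hst4 deletion than in the rtt109 deletion (2.65 and 2.39). SSB1 was 2.02 above wild type in the hst3 hst4 deletion (adjusted p = 0.000472), where HO had -0.56, while HO fell by 2.95 in the rtt109 deletion, where SSB1 had -0.63. SSB2, the near-identical copy of SSB1, had -0.16 in the hst3 hst4 deletion.

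ZPS1 had a mean of 18.7 ± 25.2 (SD, n = 2) in the hst3 hst4 deletion against 0.723 ± 0.596 (SD, n = 2) in wild type, with 36.5 and 0.952 in its libraries. Across 5183 genes, which are not independent replicates, the log2 fold change and the deposited replication timing score had a Spearman rho of -0.04 in the rtt109 deletion, -0.13 in the hst3 hst4 deletion and -0.08 between the mutants. Origin bins had a median score of 39.2 against 47.8 elsewhere, so low scores lie at origins. In the hst3 hst4 deletion the median log2 fold change was 0.11 in the 25% of genes with the lowest scores and -0.02 in the 25% with the highest.

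Further lists did not pass by camera in any comparison with all 6 libraries: homologous recombination, histone chaperones, silencing, RNA polymerase II, heat shock chaperones, glycolysis, ergosterol, the proteasome, genes of G2 and mitosis, and meiosis. Their adjusted p values in the rtt109 deletion were, in that order, 0.535, 0.219, 0.281, 0.116, 0.736, 0.701, 0.701, 0.997, 0.649 and 0.649. Single libraries decided some of these. Without replicate 1 of wild type, heat shock chaperones stood higher in the rtt109 deletion (adjusted p = 0.0153) and in the hst3 hst4 deletion (1.19e-05), and meiosis genes in the hst3 hst4 deletion (0.0411). Without replicate 2 of the hst3 hst4 deletion, meiosis genes stood higher there against wild type (0.0148) and against the rtt109 deletion (0.0430), and glycolysis genes lower than in the rtt109 deletion (0.0335). Heat shock chaperones stood higher in the hst3 hst4 deletion than in the rtt109 deletion without replicate 1 of the latter (0.0183).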
